A study of Mus musculus with 9 samples.

How the data were processed

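RNA was sequenced from 9 libraries of ICR mouse embryos cultured to the 2-cell stage, with 3 libraries in each of 3 groups and 3 embryos pooled per library, per the labels. The authors deposited raw counts of reads per gene symbol, whole numbers that were not normalised. Trim Galore and the genome build mm10 are named per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Of the 24454 genes in the table, 557 had no count in any library. Among genes with a total of at least 100 counts, 277 shared all 9 counts with another gene, in 116 distinct profiles that held 1.81% of counts, so the deposited counts do not separate those genes. Genes of the mitochondrial genome were not analysed here. No 2 libraries of a group agreed within sampling noise, with chi-square values per degree of freedom from 46.5 to 124 between libraries of a group.

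Group and replicate came from the labels. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, edgeR's filter at a minimum count of 10, robust estimation and 1 mean per group in a single fit of all 9 libraries. Benjamini-Hochberg adjustment ran over the 16964 genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.731, and the median standard error of a log2 fold change between high glucose and control was 0.78. Library totals were 14036995, 13757205 and 13991906 counts in control, 13970069, 12472285 and 12593705 under high glucose and 12051784, 16916343 and 11934924 with ZGW serum. CPM values are counts relative to the library total, scaled with the TMM factors.

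Of 29 gene lists fixed in advance, 28 had measured members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. The mean difference of a list is the mean over its members of the difference in log2 CPM between 2 groups. Separation of the groups was tested with a pseudo-F on Euclidean distances and an exact permutation over 280 assignments. Shares and scores were compared with exact permutation tests, two-sided. The return towards control was set against 100 simulations of unchanged groups that share the high glucose libraries. The tested value was changed from the correlation to the covariance of the fold changes, and simulations of their own were added for DESeq2 and for fits of 2 groups, after first results were seen.

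Genes are named by a rule: those past the threshold with a mean of at least 10 CPM and a symbol that is not a predicted or clone name, the first 10 each way by p-value. Where none pass, the 5 of lowest p-value each way are given as values, with up to 4 members of lowest p-value of each list. Members that passed adjusted over the list alone were named after the values were seen, as was Omt2a. Positions came from GENCODE annotation of GRCm38, the assembly that mm10 names. Shared sequence was measured as the percent of a gene's 50-base stretches that occur in another gene's transcripts, with a limit of 10%. That limit was lowered after the percentages were seen and before the members' differences were examined.

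Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a stricter filter of 10 counts in 6 libraries, fits of only the groups compared, the replicate number as a block, thinned counts, and leaving out each library in turn. Added after the data were seen were removal of the trend on transcript length, a permutation test of each list over the 3 groups, the 2-cell list without multi-copy members, and leaving out control replicate 1 and ZGW serum replicate 3 together. The gene test was tested on simulated data for high glucose against control, in 5 runs with 200 genes changed among 16964. The changed genes were drawn from those with a mean of at least 10 CPM. The gene test recovered 3.2% of genes changed by a factor of 2, 35.2% at a factor of 4, 78.4% at 8 and 90.4% at 16, with 20 false and 518 true calls. In 5 runs, a list shifted by -0.5 on the log2 scale was called in 5, and 0 of 135 other lists were called by camera. Genes were drawn independently of each other in these runs, so the result cannot show how often camera calls lists of correlated genes. The correlation estimated from the data was 0.32 for ribosomal proteins and 0.29 for 2-cell activation.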

Results

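Gene expression was measured by RNA sequencing in 9 libraries of ICR mouse embryos grown in culture to the 2-cell stage, when the embryonic genome is first transcribed in earnest and stored oocyte RNA is being lost. Each library was made from 3 pooled embryos. The 3 groups of 3 libraries were a control group, embryos loaded with high glucose, and embryos loaded with high glucose and treated with rat serum carrying the drug that the labels call ZGW. The labels do not say whether the first 2 groups received drug-free rat serum, so a difference between the last 2 groups includes any effect of serum itself. Library totals ranged from 11934924 to 16916343 counts, and 16964 genes had enough counts to be tested. The p-values measure the spread between these pooled samples, since the labels do not say from which matings the embryos came.

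The 3 groups lay further apart than other assignments of the same libraries to 3 groups. The pseudo-F of the distances was 1.22, the highest of the 280 possible assignments of 9 libraries to 3 groups (exact permutation p = 0.00357, the smallest the design allows). The separation was small beside the spread within groups: the mean distance between libraries was 210.4 ± 16.05 (SD, 9 pairs) within groups and 218.0 ± 16.9 (SD, 27 pairs) between groups. Control replicate 1 and ZGW serum replicate 3 lay at opposite ends of the first principal component, which held 17.8% of the variance. These were the libraries with the lowest median correlation with the other groups, at 0.802 for control replicate 1 and 0.803 for ZGW serum replicate 3.

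High glucose was compared with control to see what glucose loading changed. Ribosomal protein genes, which encode the structural proteins of the cytoplasmic ribosome, fell as a list under high glucose: 73 of the 75 measured members were lower, with a mean difference of -0.85 on the log2 scale (SD over members 0.31), a camera call that did not hold when the correlation between genes was estimated (adjusted p = 0.508 with an estimated correlation). Nuclear genes of the respiratory chain and ATP synthase fell as well, with 60 of 72 members lower and a mean difference of -0.49 (SD over members 0.64). That camera call did not hold either (adjusted p = 0.508 with an estimated correlation). Differences in log2 CPM rose weakly with transcript length across genes, which are not independent (Spearman correlation 0.19, and -0.16 with GC content). With that trend removed, the mean difference was -0.31 for the respiratory chain (camera adjusted p = 0.0383) and -0.67 for ribosomal proteins (camera adjusted p = 1.75e-13). These 2 p-values use the preset correlation, and no fit with an estimated one was made after removal of the trend. Ribosomal protein genes made up 1.87% ± 0.49 of the counts in control (SD, n = 3) and 1.08% ± 0.17 under high glucose. Markers of cumulus and granulosa cells, the somatic cells that surround the oocyte, were also lower in 9 of 12 measured members, with a mean difference of -0.84. This list did not pass the test (camera adjusted p = 0.179), and its mean difference was -0.53 without high glucose replicate 3. Only 1 of the 12 measured members was over 10 CPM in each group. Markers of blood cells were lower in 7 of 8 members, with a mean difference of -0.65 (camera adjusted p = 0.179), and those of stroma and epithelium in 9 of 13, with a mean difference of -0.56 (camera adjusted p = 0.316). The stroma and epithelium list was called without control replicate 1 (-1.44, adjusted p = 0.000527), and its mean difference was -0.09 without control replicate 3 (adjusted p = 0.782) and -0.86 without high glucose replicate 2, all by camera. The blood list's mean difference was -0.26 without high glucose replicate 1. Igfbp5 of the cumulus and granulosa list, at 4.03 ± 3.27 CPM (counts relative to the scaled library total) in control and 0.0272 ± 0.0471 under high glucose (SD, n = 3), fell when adjusted over the list alone by edgeR's quasi-likelihood test.

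Both falls passed limma's camera test with its preset correlation, at an adjusted p of 4.03e-21 for the ribosomal proteins and 5.73e-06 for the respiratory chain. Among ribosomal protein genes, 27 members fell when edgeR's quasi-likelihood p-values were adjusted over the list alone, and none did when they were adjusted over all genes with the Benjamini-Hochberg method. Rpl13, a protein of the large subunit (chromosome 8, 123102350 to 123105244, GRCm38), had 223.0 ± 60.6 CPM in control and 66.5 ± 16.4 under high glucose (SD, n = 3). Its log2 fold change was -1.75 ± 0.30 (SE), which is uncertain because 28.8% of its transcript stretches of 50 bases also occur in other genes' transcripts. Such sharing above 10% holds for 63 of the 75 members. The 12 members below that limit had a mean difference of -0.86, all 12 lower. Rpl37 had a log2 fold change of -1.66 ± 0.33, Rpl30 of -1.16 ± 0.30, and Rpl32 was at 318.0 ± 71.0 CPM in control and 158.7 ± 19.3 under high glucose (SD, n = 3). Of the respiratory chain genes, the complex I subunit Ndufb6 had a log2 fold change of -1.05 ± 0.26, the cytochrome oxidase subunits Cox8a and Cox7b of -1.17 ± 0.30 and -1.13 ± 0.32, and Atp5g1 of the ATP synthase of -0.95 ± 0.32. No respiratory chain gene passed when adjusted over the list alone.

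Lists tied most directly to glucose did not pass in this comparison. Of the glycolytic enzymes, 16 of 27 were lower (camera adjusted p = 0.490), and of the glucose transporters and insulin signalling genes 20 of 37 were higher (camera adjusted p = 0.444). The pentose phosphate, hexosamine and polyol enzymes were lower in 10 of 19 members by edgeR's log2 fold change, with a median of -0.08. Their difference in log2 CPM had a mean of 0.16 and a median of 0.24 (camera adjusted p = 0.756). The citrate cycle enzymes were higher in 20 of 35 (camera adjusted p = 0.557). Antioxidant genes were lower in 30 of 46 members, with a camera adjusted p of 0.309, and unfolded protein response genes in 18 of 33, with a camera adjusted p of 0.542. Peroxiredoxin 6 (Prdx6) had a log2 fold change of -1.24 ± 0.32. Gata4, a transcription factor of the later primitive endoderm, was at 4.76 ± 1.35 CPM in control and 20.6 ± 1.61 CPM under high glucose (SD, n = 3), and was the only member of the pluripotency and lineage list to pass adjusted over the list alone.

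No single gene passed the threshold over all genes in the comparison of high glucose with control. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16964 genes, with 1253 at an unadjusted p under 0.05 against 848.2 by chance. limma-voom called 0 and DESeq2 called 129, 55 higher and 74 lower. The groups did not overlap in 13.7% of genes, where chance gives 10%. Among genes with a mean of at least 10 CPM, those nearest to the threshold by edgeR's p-value on the higher side were Tsnax, Chac2, Hsdl1, Gata4 and Fam46c, and on the lower side Rpl13, Deb1, Rpl37, Fxyd5 and Rsph1, with adjusted p-values from 0.579 to 0.627. Tsnax, which encodes a partner of the nucleic acid binding protein translin, was at 2.04 ± 1.01 CPM in control and 21.0 ± 7.32 under high glucose (SD, n = 3), and Chac2, a glutathione-degrading enzyme, at 0.487 ± 0.359 and 23.7 ± 12.4.

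**Figure D1:**
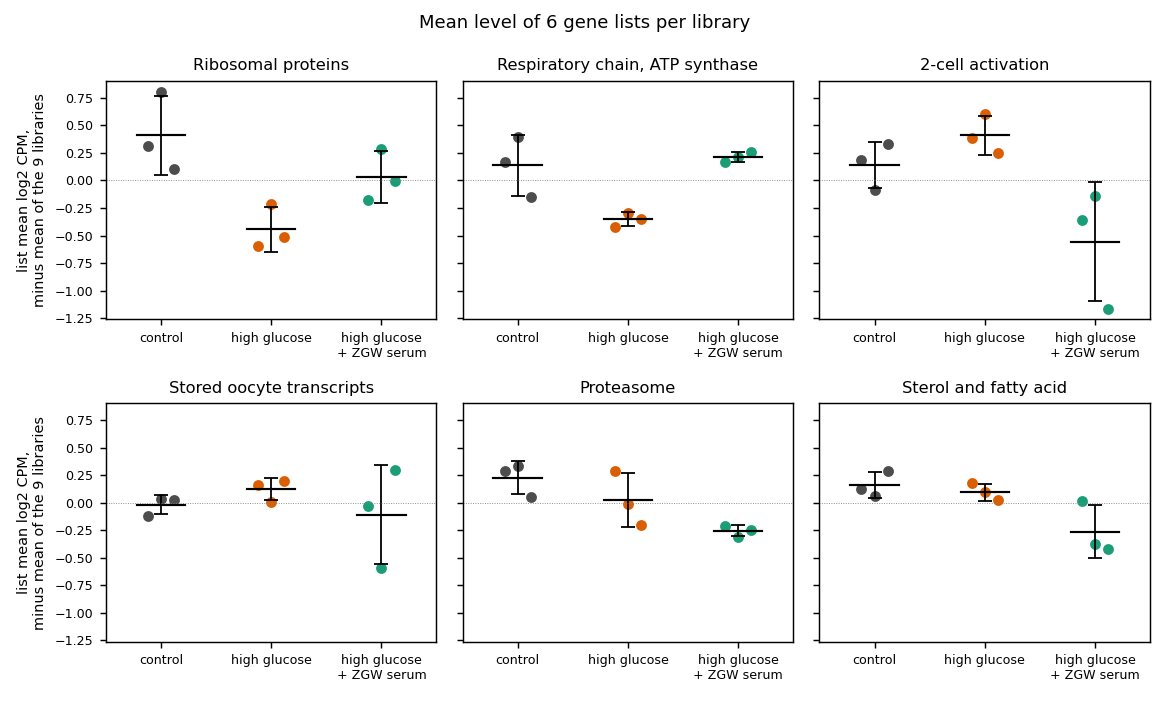
Mean log2 CPM of 6 fixed gene lists in each library, minus the mean over the 9 libraries, by group (points, libraries; horizontal lines, group means; bars, SD, n = 3). The ribosomal protein and respiratory chain lists are lowest under high glucose, and the 2-cell activation list is lowest with ZGW serum, where replicate 3 lies at -1.16.

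ZGW serum was compared with high glucose alone to see how glucose-loaded embryos differed with the serum. Genes transcribed transiently at the 2-cell stage, a programme that marks activation of the embryonic genome, fell with ZGW serum: 40 of 42 measured members were lower, with a mean difference of -0.97 on the log2 scale (SD over members 0.77). This camera call did not hold with the correlation estimated from the data (adjusted p = 0.509 with an estimated correlation). By share of counts the 2-cell activation list overlapped between the groups, at 6.24% ± 1.04 under high glucose and 3.92% ± 1.99 with ZGW serum (SD, n = 3; exact permutation p = 0.2, two-sided). ZGW serum replicate 2 was at 5.90% and high glucose replicate 3 at 5.08%. Genes of the respiratory chain and ATP synthase rose, with 59 of 72 members higher and a mean difference of 0.57 (SD over members 0.67), and ribosomal protein genes rose, with 64 of 75 higher and a mean difference of 0.48 (SD over members 0.50). Neither camera call held (adjusted p = 0.461 with an estimated correlation for the respiratory chain and 0.776 for ribosomal proteins). Across genes, differences in log2 CPM had a Spearman correlation of -0.12 with transcript length and 0.24 with GC content. With the length trend removed, the mean difference was 0.31 for ribosomal proteins (camera adjusted p = 0.00677) and 0.39 for the respiratory chain (camera adjusted p = 0.00123), both with the preset correlation only. Heat shock and chaperone genes fell, with 26 of 33 lower and a mean difference of -0.43 (SD over members 0.67), and a list of blood cell markers rose, with 6 of 8 measured members higher. These camera calls did not hold either (adjusted p = 0.586 with an estimated correlation for heat shock and 0.514 for blood markers). Members of the blood list include Hba-a1 and Hba-a2, globin genes with identical counts in each of the 9 libraries.

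With the preset correlation the camera adjusted p-values were 1.27e-10 for 2-cell activation, 4.79e-07 for the respiratory chain, 2.26e-06 for ribosomal proteins, 0.0222 for heat shock and 0.0291 for blood markers. The heat shock call ended without high glucose replicate 1, ZGW serum replicate 1 or ZGW serum replicate 3, with camera adjusted p up to 0.0993, and was lost in 7 of its 16 alternatives (adjusted p from 0.00331 to 0.586). The blood marker call ended in 5 of the 9 fits that left out 1 library, those without control replicates 1, 2 or 3, high glucose replicate 1 or ZGW serum replicate 1, with camera adjusted p up to 0.264 and a mean difference of 0.40 without high glucose replicate 1 against 0.80 in full. It was lost in 10 of its 16 alternatives (adjusted p from 0.0249 to 0.514).

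Within the 2-cell activation list, 4 members fell adjusted over the list alone and 0 over all genes by edgeR's quasi-likelihood test. They were Usp17le, Usp17lc and Usp17ld, deubiquitinases of a multi-copy family, and Ubtfl1. Usp17lc was at 66.0 ± 28.1 CPM under high glucose and 15.98 ± 0.312 with ZGW serum (SD, n = 3), a log2 fold change of -2.04 ± 0.39 (SE). Usp17le had a log2 fold change of -3.08 ± 0.58 and Usp17ld of -2.50 ± 0.54. The values of these 3 genes are uncertain, because Usp17lc shares 44.7%, Usp17le 30.8% and Usp17ld 51.1% of transcript stretches of 50 bases with other genes. Ubtfl1, which shares 3.36%, was at 135.1 ± 68.4 CPM under high glucose and 47.3 ± 7.94 with ZGW serum, a log2 fold change of -1.51 ± 0.36. Without ZGW serum replicate 3 the list's mean difference was -0.64 (camera adjusted p = 2.15e-05), and without that library and control replicate 1, which both lay apart, it was -0.63 (camera adjusted p = 4.35e-05).

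Among the energy genes, 3 rose adjusted over the list alone, and 0 did over all genes, by edgeR's quasi-likelihood test. They were Cox7a2 of cytochrome oxidase, with a log2 fold change of 1.49 ± 0.27, Ndufa4 with 1.18 ± 0.23 and Atp5l of the ATP synthase with 1.39 ± 0.31. Cox7a2 was at 271.2 ± 32.5 CPM under high glucose and 763.8 ± 199.0 with ZGW serum (SD, n = 3). Of the ribosomal protein genes 2 rose adjusted over the list alone, Rpl32 with a log2 fold change of 1.19 ± 0.25 and Rpl37 with 1.42 ± 0.33. Both values are uncertain, with 26.1% and 26.7% of their transcript stretches shared with other genes. Rpl13 is an exception among the ribosomal protein genes, at 66.5 ± 16.4 CPM under high glucose and 51.1 ± 3.17 with ZGW serum. The co-chaperone Stip1, which links Hsp70 to Hsp90, was the member of the heat shock list that fell adjusted over the list alone. It was at 121.7 ± 15.8 CPM under high glucose and 51.2 ± 6.27 with ZGW serum. Citrate cycle enzymes had 25 of 35 members lower, a mean difference of -0.43 that did not pass (camera adjusted p = 0.0721), and Idh3a among them had a log2 fold change of -1.25 ± 0.31.

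Stored oocyte transcripts did not pass as a list between ZGW serum and high glucose alone. Of 56 measured members 37 were lower, with a mean difference of -0.23 (camera adjusted p = 0.0721). The result rested on single libraries: the mean difference was -0.41 without ZGW serum replicate 3 (adjusted p = 0.00104) and -0.30 without high glucose replicate 2 (adjusted p = 0.0296), where the list fell by camera, and 0.01 without ZGW serum replicate 2 (adjusted p = 0.939). Without control replicate 1 and ZGW serum replicate 3 together it was -0.40 (camera adjusted p = 0.00121). In contrast to the list, Omt2b and Oosp1 were higher, with log2 fold changes of 1.02 ± 0.23 and 0.89 ± 0.21 and passed edgeR's quasi-likelihood test adjusted over the list alone. Omt2a was added to Omt2b after its values were seen. The share of counts in both together ran from 3.00% to 4.90% under high glucose, from 5.36% to 6.11% in control and from 7.99% to 9.48% with ZGW serum. The 10 most counted genes held 12.5% ± 0.697 of counts under high glucose and 17.02% ± 1.41 with ZGW serum (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give).

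edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16964 genes between ZGW serum and high glucose alone, with 1473 at an unadjusted p under 0.05 against 848.2 by chance. limma-voom called 0 and DESeq2 called 241, 86 higher and 155 lower. Groups did not overlap in 17.4% of genes, where chance gives 10%. Among genes with a mean of at least 10 CPM, the lowest p-values on the higher side belonged to Snrpg, Cox7a2, Rps27l, Nop10 and Hypk, and on the lower side to Paip1, Usp17le, Usp17lc, Stip1 and Fbxo5, each with an edgeR adjusted p of 0.370. Snrpg, a core spliceosomal protein, was at 1076 ± 88.9 CPM under high glucose and 3112 ± 1020 with ZGW serum (SD, n = 3), and Fbxo5, an inhibitor of the anaphase-promoting complex, at 255.6 ± 56.2 and 98.2 ± 11.0.

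**Figure D2:**
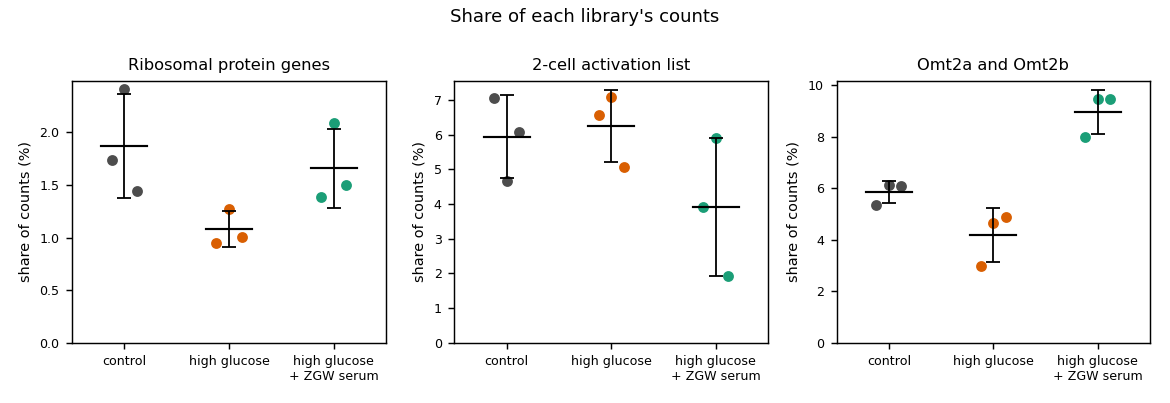
Percent of each library's counts held by ribosomal protein genes, by the 2-cell activation list and by Omt2a with Omt2b, by group (points, libraries; horizontal lines, group means; bars, SD, n = 3; axes start at 0). The ribosomal protein share is 1.87% in control, 1.08% under high glucose and 1.66% with ZGW serum, and each ZGW serum library exceeds each other library in Omt2a and Omt2b. The 2-cell activation share is 5.94% in control, 6.24% under high glucose and 3.92% with ZGW serum, with overlap between the groups.

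Embryos with high glucose and ZGW serum were compared with controls to see how far they stood from the control group. The 2-cell activation list fell, with 33 of 42 members lower and a mean difference of -0.70 on the log2 scale (SD over members 0.98). This camera call did not hold with the correlation estimated (adjusted p = 0.648 with an estimated correlation). Proteasome subunits fell, with 23 of 31 lower and a mean difference of -0.48 (SD over members 0.65), and sterol and fatty acid genes fell, with 27 of 38 lower and a mean difference of -0.42 (SD over members 1.12). Neither camera call held (adjusted p = 0.648 with an estimated correlation for the proteasome and 0.589 for sterol and fatty acid genes). Ribosomal protein genes fell, with 61 of 75 lower and a mean difference of -0.38 (SD over members 0.51), a camera call that did not hold either (adjusted p = 0.805 with an estimated correlation). Respiratory chain genes did not pass, with 43 of 72 higher and a mean difference of 0.08 (camera adjusted p = 0.634). Cumulus and granulosa markers were lower in 9 of 12 members, with a mean difference of -1.03, and did not pass (camera adjusted p = 0.173). Stroma and epithelium markers were lower in 11 of 13 members, with a mean difference of -0.59 (camera adjusted p = 0.345), which ran from -1.41 without control replicate 1 (adjusted p = 0.00105) to -0.12 without control replicate 3. That list was also called without ZGW serum replicate 2 (-1.12, camera adjusted p = 0.0407).

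By camera with the preset correlation the adjusted p-values were 2.27e-06 for 2-cell activation, 0.00624 for the proteasome, 0.0132 for sterol and fatty acid genes and 0.000539 for ribosomal proteins. The ribosomal protein call ended without control replicate 2 (mean difference -0.18, adjusted p = 0.319) or ZGW serum replicate 1, and the proteasome call without control replicate 2 (-0.43, adjusted p = 0.0569). Without ZGW serum replicate 3 the mean difference of the 2-cell activation list was -0.37 (adjusted p = 0.00467), and without control replicate 1 as well it was -0.35 (adjusted p = 0.0195). The sterol and fatty acid call ended without control replicate 3 (adjusted p = 0.0590) or ZGW serum replicate 2 (adjusted p = 0.0515), all by camera.

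Paip1, which encodes a poly(A)-binding protein partner that promotes translation (chromosome 13, 119428601 to 119458218, GRCm38), came nearest to the threshold over all genes. It was at 3103 ± 644.2 CPM in control, 1744 ± 526.2 under high glucose and 515.3 ± 80.6 with ZGW serum (SD, n = 3). Its log2 fold change between ZGW serum and control was -2.59 ± 0.29 (SE), with an adjusted p of 0.0511 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With limma-voom, no filter on low counts, a stricter filter or counts thinned to the smallest library, it passed, with adjusted p-values of 0.0184, 0.0325, 0.0191 and 0.0469. With all libraries or all but 1, the adjusted p over its alternatives ran from 1.45e-12 with DESeq2 to 0.493 without ZGW serum replicate 3. Without control replicate 1 and ZGW serum replicate 3 together, the lowest edgeR adjusted p of any gene was 0.726.

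Members that fell adjusted over the list alone by edgeR's quasi-likelihood test were 1 for 2-cell activation (Usp17le), 1 for the proteasome, 3 for sterol and fatty acid genes and 3 for ribosomal proteins, and 0 of these passed over all genes. Psmc6, an ATPase of the proteasome's regulatory particle, was at 147.8 ± 6.42 CPM in control and 35.4 ± 7.32 with ZGW serum (SD, n = 3), a log2 fold change of -2.06 ± 0.34 (SE). The desaturase Scd1 had a log2 fold change of -3.04 ± 0.66, the squalene synthase Fdft1 of -0.96 ± 0.24 and Insig1, a regulator of sterol synthesis, of -1.08 ± 0.29. Of the ribosomal proteins, Rpl13 had a log2 fold change of -2.13 ± 0.30, Rpl6 of -1.40 ± 0.34 and Rpl7 of -2.21 ± 0.54. All 3 are uncertain, with 28.8%, 64.3% and 38.1% of their transcript stretches shared with other genes. Outside the called lists, Stip1 (-1.10 ± 0.25), Prpf38a (-1.53 ± 0.29) and Snrpc (-1.71 ± 0.36) fell adjusted over the list alone, as did Igfbp5 and Krt18 of the cumulus and granulosa list. Igfbp5 was at 0.0881 ± 0.0805 CPM with ZGW serum, and Krt18 at 30.82 ± 19.03 CPM in control and 2.66 ± 2.66 with ZGW serum (SD, n = 3). Tsnax was at 18.2 ± 1.98 CPM with ZGW serum against 2.04 ± 1.01 in control and 21.0 ± 7.32 under high glucose alone.

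edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16964 genes between ZGW serum and control, with 1673 at an unadjusted p under 0.05 against 848.2 by chance. limma-voom called 1, Paip1, and DESeq2 called 348, 99 higher and 249 lower. Groups did not overlap in 16.3% of genes, where chance gives 10%. Beside Paip1, Rpl13 and Psmc6, the lowest p-values among genes with a mean of at least 10 CPM on the lower side belonged to Celf4 and Cd24a, and on the higher side to Tsnax, Cypt12, Chac2, Ptdss1 and Tram2.

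**Figure D3:**
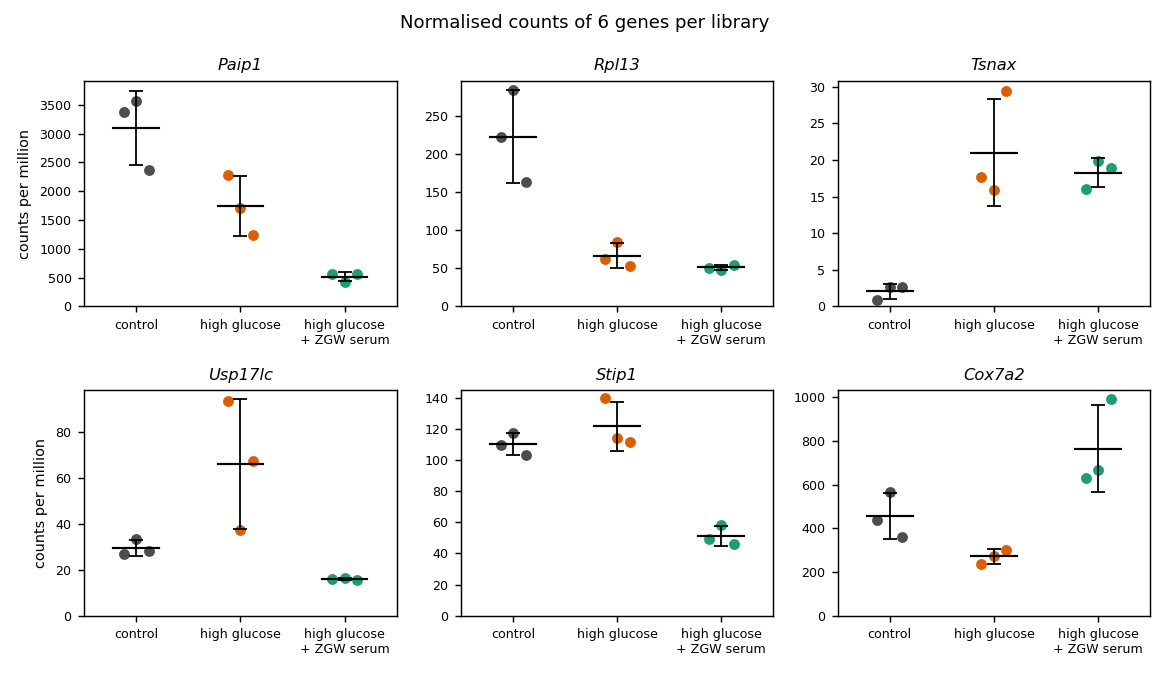
Normalised CPM of Paip1, Rpl13, Tsnax, Usp17lc, Stip1 and Cox7a2 in each library, by group (points, libraries; horizontal lines, group means; bars, SD, n = 3; axes start at 0). Paip1 has group means of 3103, 1744 and 515.3 CPM, differences that did not pass over all genes by edgeR, and Tsnax has 2.04, 21.0 and 18.2 CPM.

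The design also asks whether ZGW serum turned back the changes of glucose loading. With no gene past the threshold in either comparison, 0 genes passed in both with opposite signs by edgeR's quasi-likelihood test, while 276 genes had an unadjusted p under 0.05 in both with opposite signs and 12 with the same sign. Independent lists would give 54.8 with opposite signs. Simulated unchanged groups that share the high glucose libraries gave 174.4 on average with opposite signs (155 to 205 in 20 simulations). The 276 observed lay above that range. With the same sign, the simulations gave 1.7 on average, fewer than the 12 observed. Of the 1253 genes at an unadjusted p under 0.05 between high glucose and control, 81.4% had the opposite sign with ZGW serum, less than the 88.4% on average in those simulations (86.0% to 91.2%). Over all 16964 genes the log2 fold changes of the 2 comparisons had a correlation of -0.41, against -0.50 on average in 100 simulations, and a covariance of -0.560 against -0.549 (-0.590 to -0.510). The covariance thus lay within the simulated range with all libraries and the chosen settings, but below all simulated values in 11 of its 16 alternatives. These include the replicate number as a block (-0.73) and the fits without 1 library other than high glucose replicate 1 (-1.32 to -0.73). The correlation was below the simulated mean in 0 of the 16 alternatives. The lower covariances thus came with a wider spread of fold changes than simulated, and do not by themselves show a return. Genes were simulated independently, so the simulated range can be too narrow for correlated genes. The 3 high glucose libraries enter both comparisons. The ribosomal protein list had means of 7.52 ± 0.36 log2 CPM in control, 6.67 ± 0.20 under high glucose and 7.15 ± 0.24 with ZGW serum (SD, n = 3). The libraries with ZGW serum overlapped those of control (exact permutation p = 0.2, two-sided). The respiratory chain list with ZGW serum had a mean that differed from control by less than the spread between control libraries (5.13 ± 0.27 log2 CPM in control, 4.64 ± 0.06 under high glucose and 5.21 ± 0.05 with ZGW serum, SD, n = 3).

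The score of 2-cell activation minus stored oocyte transcripts did not separate the groups. It was 0.12 ± 0.24 in control, 0.25 ± 0.28 under high glucose and -0.49 ± 0.96 with ZGW serum (SD, n = 3). Exact permutation p-values, two-sided, were 0.6 for high glucose against control, 0.3 for ZGW serum against high glucose and 0.4 for ZGW serum against control, where 0.1 is the smallest that 3 against 3 can give. ZGW serum replicate 3 lay at -1.50 and replicate 2 of the same group at 0.41.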

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

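Removal of the length trend, the joint removal of control replicate 1 and ZGW serum replicate 3, and the 2-cell list without multi-copy members were chosen after the results were seen. The count of genes past the threshold, 0 in each comparison by edgeR (1253, 1473 and 1673 at an unadjusted p under 0.05), was 129, 241 and 348 with DESeq2 for high glucose against control, ZGW serum against high glucose and ZGW serum against control. For the last it was 1 with limma-voom, no filter, the stricter filter or thinned counts, each time Paip1. The number of lists called, 2, 5 and 4, was 0 in each comparison with an estimated correlation and with fry. For ZGW serum against high glucose it was 3 with the length trend removed, and leaving out 1 library gave 2 to 3, 3 to 6 and 2 to 6 lists. Without control replicate 1 and ZGW serum replicate 3 together, 8 lists were called for ZGW serum against control, with oocyte transcripts (-0.32, adjusted p = 0.0269), heat shock (-0.40, 0.0327), cell cycle (-0.21, 0.0484) and stroma and epithelium (-1.01, 0.0195) gained, all lower by camera. The same libraries out gained stroma and epithelium (-1.45) for high glucose against control, and oocyte transcripts (-0.40) while losing heat shock and blood for ZGW serum against high glucose. Lists gained in fits without 1 library were stroma and epithelium and sex-linked genes for high glucose against control, oocyte transcripts and proteasome for ZGW serum against high glucose, and heat shock, stroma and epithelium, sex-linked genes and ribosome biogenesis for ZGW serum against control. The covariance of the return was -0.56 and lay below all simulated values with limma-voom (-0.67), with no filter (-1.28) and with the replicate number as a block (-0.73), and leaving out 1 library gave -1.32 to -0.73 in the 8 fits that did so. Each then had p = 0.0099, the smallest the permutations of 100 simulations can give, and without high glucose replicate 1 it was -0.999 and within the simulated range. Genes were simulated independently, so that range can be too narrow for correlated genes. The other 4 alternatives were not below all simulated values. The covariance was -0.302 with the stricter filter (simulated mean -0.333), -0.561 with DESeq2 (-0.717) and -0.386 with only the 2 groups compared (-0.404), all 3 nearer 0 than the simulated mean, and -0.560 with RLE (-0.547). The score difference between high glucose and control, 0.13, was -0.01 without control replicate 2 and -0.0252 without high glucose replicate 2, and ran from -0.0252 to 0.24. Leaving out 1 library moved that between ZGW serum and high glucose, -0.73, from -1.18 to -0.23, and that between ZGW serum and control, -0.61, from -1.06 to -0.10. The separation of the groups held in its 3 alternatives. The cause of these changes was not tested. Of 1054 values of named genes under alternatives, 1054 kept their direction and 55 were past the threshold, 52 of them with DESeq2. Equal replicate numbers did not clearly pair the libraries. Correlations of their deviations ran from -0.01 to 0.10 for equal numbers, with 1 of 9 over 0.1. For other numbers they ran from -0.095 to 0.046, with 0 of 18 over 0.1. Of 18 best matches 10 had the same number, so a weak pairing stays open. The block changed no other call of genes or lists. In the simulated data of this depth and spread, a gene with a mean of at least 10 CPM that changed by a factor of 2 was recovered in 3.2% of cases.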

Other observations

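Chosen after the result was seen were the tests of near-identical copies, of a single library, of stored oocyte transcripts and of cumulus cell RNA, the splits for genes, and the removal of the length trend. With ZGW serum against high glucose alone, the core proteins Snrpg and Snrpe had log2 fold changes of 1.53 ± 0.27 and 1.41 ± 0.33 (SE) and passed edgeR's quasi-likelihood test adjusted over the list alone, while the list of 43 spliceosome genes did not pass (21 higher, camera adjusted p = 0.893). Against control, Prpf38a and Snrpc were lower by the same test, with log2 fold changes of -1.53 ± 0.29 and -1.71 ± 0.36 (list camera adjusted p = 0.634). Of 2 proteins of small nucleolar particles, Nop10 was higher with ZGW serum than with high glucose alone, at 1.28 ± 0.24, and Nop56 lower, at -1.18 ± 0.30, both adjusted over the list alone (list camera adjusted p = 0.404). Hexokinase 2 (Hk2) was at 11.9 ± 3.00 CPM under high glucose and 0.974 ± 0.538 with ZGW serum (SD, n = 3), the only glycolytic enzyme to pass adjusted over the list alone (list camera adjusted p = 0.893). The p53 target Rps27l was higher with ZGW serum, at 1.25 ± 0.24.

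Lists of cell death, DNA repair, cell division and chromatin genes did not pass in any comparison with all 9 libraries. The cell cycle list passed for ZGW serum against control without control replicate 1 and ZGW serum replicate 3 (mean difference -0.21, camera adjusted p = 0.0484). For ZGW serum against high glucose the camera adjusted p was 0.893 for apoptosis, 0.893 for DNA repair, 0.670 for cell cycle, 0.404 for chromatin modifiers, 0.714 for autophagy and 0.974 for p53 targets. Imprinted genes (0.669), pluripotency and lineage genes (0.961), blastocyst genes (0.861), stromal and epithelial markers (0.974) and sex-linked genes (0.974) did not pass by camera either. In that comparison the median and mean difference in log2 CPM had opposite signs for the apoptosis, p53 and pluripotency lists. For the stroma, sex-linked, spliceosome, glycolysis and unfolded protein response lists these had the same sign. Only the median of edgeR's log2 fold changes had the opposite sign there. Without control replicate 1 the stromal and epithelial list was lower against control with high glucose (-1.44, adjusted p = 0.000527) and with ZGW serum (-1.41, adjusted p = 0.00105), and without control replicate 3 the sex-linked list was higher (1.40, adjusted p = 0.0206, and 1.45, adjusted p = 0.0140), all by camera. Over the 3 groups, exact permutation of each list's mean gave p = 0.00714 for 2-cell activation, 0.0143 for ribosomal proteins and for the citrate cycle, 0.025 for the respiratory chain, 0.0321 for sterol and fatty acid genes and 0.0429 for the proteasome. None passed Benjamini-Hochberg adjustment over the lists (smallest 0.133). With the length trend removed, exact permutation gave 0.0107 for 2-cell activation, 0.0607 for ribosomal proteins, 0.0571 for the respiratory chain, 0.0393 for the citrate cycle, 0.0464 for sterol and fatty acid genes and 0.1 for the proteasome. None of these passed Benjamini-Hochberg adjustment over the lists either (smallest 0.283).

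Ribosomal protein and respiratory chain genes were lower with high glucose and higher with ZGW serum by camera with its preset correlation, and none of these 4 calls held (adjusted p = 0.508 and 0.776 with an estimated correlation for ribosomal proteins, 0.508 and 0.461 for the respiratory chain). Length, GC content and shared reads were argued against as the whole cause: each list's median lay beyond 10000 lists matched on expression and either property (percentile 0 in the first comparison and 100 in the second), and members without near-identical copies moved by -0.86 and 0.65 for ribosomal proteins and by -0.46 and 0.52 for the respiratory chain. With the length trend removed the mean differences shrank to -0.67 and 0.31 for ribosomal proteins and to -0.31 and 0.39 for the respiratory chain. RNA of cumulus or granulosa cells stays open for the ribosomal proteins, since that list was lower by 0.84 with high glucose (-0.84, SD within groups 0.46) and differed by -0.19 with ZGW serum, where its median (0.17) and its test had the opposite sign. In refits without 1 library the first value reached -0.53 (without high glucose replicate 3), and the second ran from -0.43 (without high glucose replicate 1) to -0.09 (without high glucose replicate 2). High glucose replicate 2 was an exception, with that list at 0.52 above its mean over the libraries, and 1 of its 12 measured genes is in another list too. Of the 27 listed markers only 12 had enough counts to be tested, and only 1 was over 10 CPM in each group. The list mean thus rests largely on genes near the floor and cannot decide the question. A need for Vim to be lower too was added after its levels were seen, and turned a reading in favour of that source into an open one, although Vim was at 2.54 ± 3.70 CPM in control and 6.10 ± 4.46 under high glucose (SD, n = 3), within its spread. Serpine2, the list's most abundant gene, was at 52.8, 37.9 and 36.7 CPM in control, under high glucose and with ZGW serum.

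The 2-cell activation genes were lower with ZGW serum (adjusted p = 0.509 with an estimated correlation, by camera). This may reflect the treatment, the serum or slower or faster development, which the design does not separate. These genes are transcribed transiently, so lower levels alone do not tell slower from faster development. Against shared reads as the cause, the 11 members without near-identical copies had a mean difference of -0.74 (-1.32 to -0.17, 95% interval over members, which are not independent), and against transcript length the list's median lay at percentile 0 of matched lists. GC content was not tested for this list. Across genes, differences in log2 CPM in this comparison correlated more strongly with GC content (Spearman 0.24) than with length (-0.12). Leaving out any 1 of the 6 libraries gave a difference of -0.66 or lower with the scaling of all 9 libraries, beyond the SD within groups of 0.35. Slower loss of stored oocyte transcripts stays open, since the oocyte list differed by -0.23, less than its SD within groups of 0.27. That value rests on single libraries: in refits it was -0.41 without ZGW serum replicate 3, when the list was called lower (camera adjusted p = 0.00104), and 0.01 without ZGW serum replicate 2 (adjusted p = 0.939).

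Opposite changes under glucose loading and ZGW serum could come from the high glucose libraries that both comparisons share. The covariance of -0.56 lay within the simulated range, which by the range rule written beforehand counts in favour of that explanation. The use of the covariance in place of the correlation was itself chosen after first results. After 11 of 16 alternatives were seen to lie below all simulated values, the reading was changed to open, and the first reading is given here too. The correlation lay below the simulated mean in 0 of 16 alternatives. The lower covariances thus came with a wider spread of fold changes than in the simulations, which drew genes independently. By themselves these covariances do not show a return towards control. The 276 genes with an unadjusted edgeR p under 0.05 in both comparisons and opposite signs lay above the 155 to 205 of 20 simulations. The 12 with the same sign were also more than the simulated mean of 1.7. Since genes were simulated independently, these counts do not decide between a return and the shared libraries.

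The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes past the threshold by edgeR the real value and the highest other were 0 and 0 in each comparison, so that 10 of 10 splits gave as many (1253, 1473 and 1673 at an unadjusted p under 0.05, with at most 1000, 917 and 1097 in other splits, and 129, 241 and 348 by DESeq2 for the real groups). For lists, the real value was 2 and the highest other 5 for high glucose against control (6 splits gave as many). It was 5 and 4 for ZGW serum against high glucose (1 split), and 4 and 6 for ZGW serum against control (3 splits).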
